A study of Ovis aries with 29 samples.

How the data were processed

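RNA-seq was run on caruncular endometrium, the raised areas of the sheep uterine lining to which the placenta attaches, from 29 ewes with 1 library per ewe. Per the labels, RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq mRNA kit. Per the submitters' processing notes, reads were aligned with STAR and assigned to genes with featureCounts. The versions, the genome build, the annotation and the strand setting were not given in the sources used here, so reads of overlapping or antisense genes and of near-identical gene copies could not be told apart. The authors deposited raw read counts per gene, with the same 20921 Ensembl sheep gene IDs in each file and no row without a gene.

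The deposited files do not pair the IDs with names. The RefSeq gene table at hand (assembly ARS-UI_Ramb_v3.0) matched 0 of the 20921 IDs, so genes are given by ID, without position or function. The 40 gene lists fixed before the data were examined, which held the cell type markers, and the planned reports of PGR, ESR1 and OXTR could therefore not be used. For the same reason the rule for named genes was applied without its condition on a gene symbol. As fixed beforehand, it asked for up to 10 genes that rose and 10 that fell per comparison, and, where fewer than 5 passed, for the 5 of smallest p that did not. After the counts were seen, this was lowered to 2 in each direction and 1 that did not pass, since bare IDs say little. The rule took genes past the threshold with an average log2 CPM of at least 1 and the largest fold changes. The libraries of both groups had to lie fully apart or, for the mean of the 3 diets, the group means had to differ in the same direction in each diet. Where fewer than 5 genes passed, those that passed were named together with the gene of smallest p among those that did not. This gene also had to have an average log2 CPM of at least 1, so each smallest p given below holds within that limit.

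The titles split the libraries by diet, day of the cycle and treatment into 7 groups. The design text gives diets at 100, 200 and 60% of requirement. Its control diet carries another abbreviation than the titles (CF and NF), and both were taken as the same diet by elimination. Libraries are named by their titles. No number at the end of a title recurred, so libraries were not paired. Saline libraries carried numbers from 3 to 88 and FSH libraries from 101 to 147, so any difference in handling that follows these numbers cannot be told apart from the treatment.

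Library totals ranged from 6.53 to 20.9 M counts (M, 1e+06). Day 5 libraries held 11.1 to 20.9 M, control-fed day 10 saline libraries 10.6 to 11.0 M and control-fed FSH libraries 8.88 to 14.0 M. Overfed saline libraries held 8.38 to 11.1 M, overfed FSH libraries 6.53 to 8.89 M, underfed saline libraries 7.00 to 10.4 M and underfed FSH libraries 6.87 to 7.41 M. Across genes, pairs of libraries within a group had a median Spearman correlation of 0.966 (47 pairs) and pairs between groups 0.954 (359 pairs). The lowest chi-square per degree of freedom of a pair within a group was 10.5, so no library repeated another of its group within sampling noise. Pairs between groups were not tested in this way.

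Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 14734, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 29 libraries, and 12 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. Fold changes are log2 values, with a standard error computed from the estimate and its F statistic. Values per library are CPM or log2 CPM with a prior count of 2. Ratios of genes with few counts were computed from pooled CPM, with an exact (Clopper-Pearson) 95% interval that covers counting error only. A group total of 0 counts was given a floor of 3 counts over the group.

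The share of squared distance between 2 groups was the part of the summed squared Euclidean distance between libraries (log2 CPM, all tested genes) that lies between the group means, tested against all splits of the same libraries. The day score of a library was its mean log2 CPM over the genes higher on day 10 minus that over the genes lower on day 10. The median share over the splits of a comparison was 11.2 to 17.1%, so shares from groups of different sizes are not on one scale. The distance measure was chosen after the gene counts had been seen.

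The fit was tested on simulated data drawn from the real means and library totals, with 100 genes changed 2-fold and 100 changed 4-fold. For day 10 against day 5, 55% of the 2-fold and 88% of the 4-fold changes among 14734 genes were recovered. For the 3 diet comparisons under saline, 47 to 57% and 77 to 86% were recovered. For FSH within a diet the shares were 42 to 51% and 78 to 87%, and for its mean over diets 79 and 98%. The differences of the FSH effect between diets had the lowest recovery, 20 to 23% and 61 to 62%. False calls made up 2.88 to 7.59% of calls. The simulated genes varied independently of one another, so differences shared by many genes of a library were left out. The shares recovered and the false calls therefore need not hold for the real libraries.

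The alternatives were median-of-ratios size factors, no filter and a stricter filter (at least 1 CPM in at least 50% of libraries), DESeq2 1.42.0, and limma 3.58.1 with voom and sample weights. Further ones were a fit to the compared groups alone, an added minimum log2 fold change of 1, and leaving out each library. Another 4 were chosen after the data were seen: leaving out the 3 libraries with a TMM factor under 0.8, the bias-adjusted deviances of edgeR, voom without weights, and counts thinned to the smallest total. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.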

Results

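Gene expression was measured in the caruncular endometrium of ewes that were control-fed, overfed or underfed and given follicle-stimulating hormone (FSH), which stimulates several ovarian follicles to grow, or saline. FSH was given at 5, 4 and 3 mg per injection on days 13, 14 and 15 of the oestrous cycle, and tissue was taken on day 5 or day 10 of the next cycle. Day 5 was sampled only in control-fed ewes given saline (n = 5). On day 10 there were 4 control-fed, 5 overfed and 4 underfed ewes given saline, and 4 control-fed, 4 overfed and 3 underfed ewes given FSH. Libraries carry their titles as names, which give the diet (NF for control-fed, OF, UF), the day, C for saline or FSH, and a number. The 29 libraries held 6.53 to 20.9 M counts each (M, 1e+06), and 14734 genes were tested.

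The first principal component carried 19.2% of the variance and the second 11.8%. The 5 day 5 libraries lay between 22.3 and 67.5 on the first component, together with OF_10_C_28 (35.4) and UF_10_FSH_147 (62.0). The 4 control-fed FSH libraries lay between -28.2 and -46.3, and so did UF_10_C_67 (-44.6) and UF_10_FSH_136 (-28.4). In 3 libraries the 100 most abundant genes took a larger share of the counts than in the others. These were NF_10_FSH_110 (33.4%), NF_10_FSH_137 (34.6%) and UF_10_C_67 (34.3%), against 19.6 to 26.7% in the rest.

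**Figure D1:**
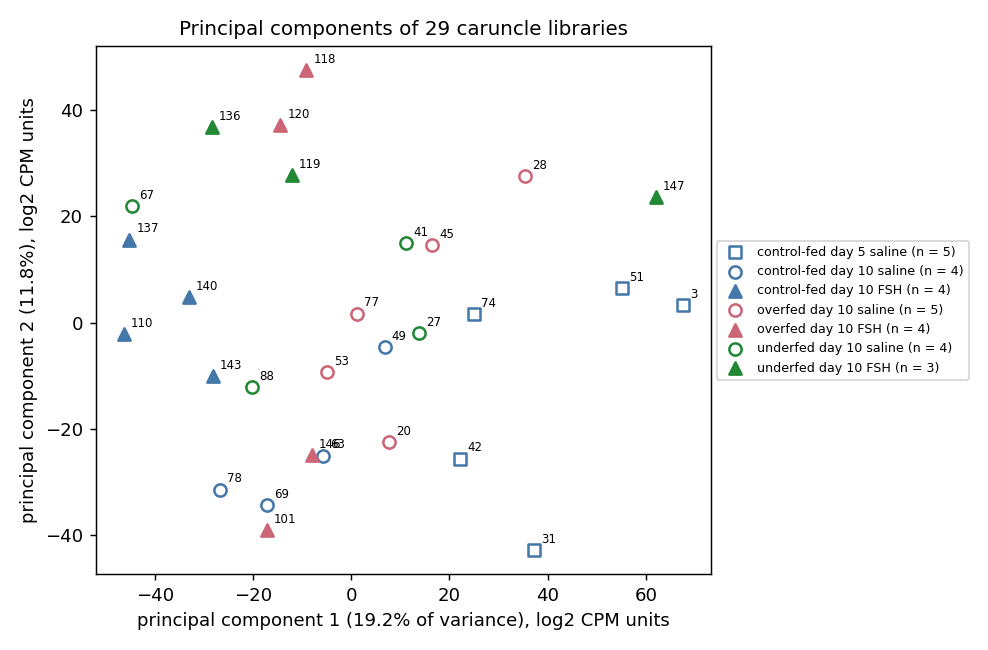
First and second principal components of log2 CPM for the 29 libraries, each point a library marked with the number in its title, coloured by diet, with squares for day 5, open circles for day 10 saline and filled triangles for FSH. UF_10_FSH_147 lies at 62.0 on the first component, among the day 5 libraries (22.3 to 67.5).

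The comparison of day 10 with day 5 in control-fed ewes given saline asked how the caruncle changes over the luteal phase, when progesterone rises. ENSOARG00000019185 rose from 1.21 ± 1.72 CPM on day 5 (SD, n = 5) to 30.5 ± 3.92 CPM on day 10 (SD, n = 4), a log2 fold change of 4.72 (SE 0.95, edgeR adjusted p = 0.00932). ENSOARG00000006084 rose from 10.6 ± 5.2 to 200.3 ± 57.3 CPM, a log2 fold change of 4.23 (SE 0.98, edgeR adjusted p = 0.0222). ENSOARG00000007957 fell from 1835 counts summed over the 5 day 5 libraries to 2 over the 4 day 10 libraries (log2 fold change -8.49, SE 1.54, edgeR adjusted p = 0.00574). Its pooled CPM was 536 times lower on day 10, with an exact interval of 148 to 4429. On day 5 it ranged from 2.59 to 43.9 CPM between ewes. ENSOARG00000004092 fell from 467 summed counts to 1 (log2 fold change -7.31, SE 1.73, edgeR adjusted p = 0.0251), 273 times lower with an exact interval of 48.7 to 10797. Both intervals cover counting error only and not the spread between ewes.

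In that comparison 402 genes passed an adjusted p of 0.05 with edgeR, 36.3% of them higher and 63.7%, or 256 genes, lower on day 10. The count was 903 with DESeq2, 988 with weighted limma, 618 with the bias-adjusted deviances of edgeR, 256 with the stricter filter and 197 from the compared groups alone, and more genes fell than rose in each of these. The genes that rose had a median log2 fold change of 0.93 and those that fell -1.90, and both medians were the same with genes at 0 counts in one group placed at their floor. Of the genes that rose, 1 had no count on day 5 and 2 had 1 to 3 counts; of those that fell, 2 had no count on day 10 and 11 had 1 to 3. Without them, 29 genes rose and 107 fell more than 4-fold. The libraries of both days lay fully apart for 323 of the 402 genes, and for 8.86% of all tested genes, where chance gives 1.59%. Between the days lay 29.6% of the squared distance (exact permutation p = 0.00794, the smallest that 126 splits allow, adjusted p = 0.0714 over 9 comparisons). Left-out libraries also moved the edgeR count, which fell to 132, 68 and 102 without NF_10_C_63, NF_10_C_69 or NF_10_C_78, and to 80, 237 and 261 without NF_5_C_3, NF_5_C_42 or NF_5_C_51, and it rose to 621 without NF_5_C_74. The call of ENSOARG00000006084 was lost without NF_10_C_69, NF_10_C_78, NF_5_C_3 or NF_5_C_42, and that of ENSOARG00000004092 without any of the 4 day 10 libraries or without NF_5_C_3. With limma without sample weights, the calls of ENSOARG00000019185, ENSOARG00000007957 and ENSOARG00000004092 were lost (adjusted p = 0.0620, 0.0740 and 0.0895).

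**Figure D2:**
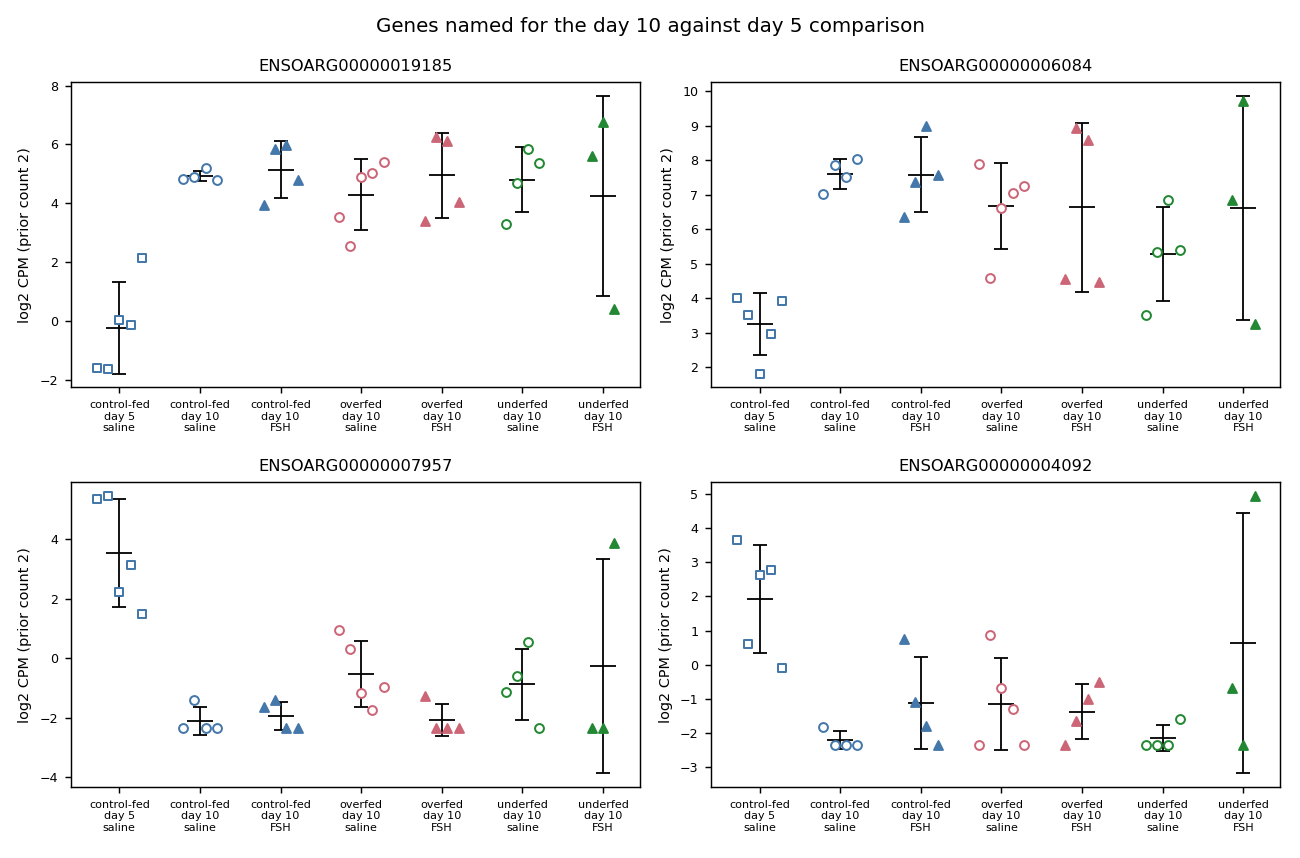
Log2 CPM (prior count 2) of the genes named for day 10 against day 5 in each library of the 7 groups, with bars at the mean and SD. ENSOARG00000019185 and ENSOARG00000006084 are higher and ENSOARG00000007957 and ENSOARG00000004092 lower in all 4 control-fed day 10 saline libraries than in the 5 day 5 libraries, and UF_10_FSH_147 stands apart from the other FSH libraries of its group in all 4 panels.

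The day score set the libraries of the other groups on the scale of these 402 genes. The control-fed groups that defined the score had means of -0.57 ± 0.77 on day 5 and 2.63 ± 0.35 on day 10 (SD, n = 5 and 4). On day 10, saline libraries scored 1.83 ± 0.59 in overfed ewes (SD, n = 5) and 1.72 ± 0.16 in underfed ewes (SD, n = 4), which did not differ (difference 0.11, exact two-sided permutation p = 0.746). Scores under FSH were 2.11 ± 0.22 in control-fed and 2.11 ± 0.05 in overfed ewes (SD, n = 4 each). Of the underfed FSH libraries, UF_10_FSH_119 and UF_10_FSH_136 scored 1.72 and 2.43, and UF_10_FSH_147 scored -0.50, inside the range of the day 5 libraries (-1.67 to 0.48).

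**Figure D3:**
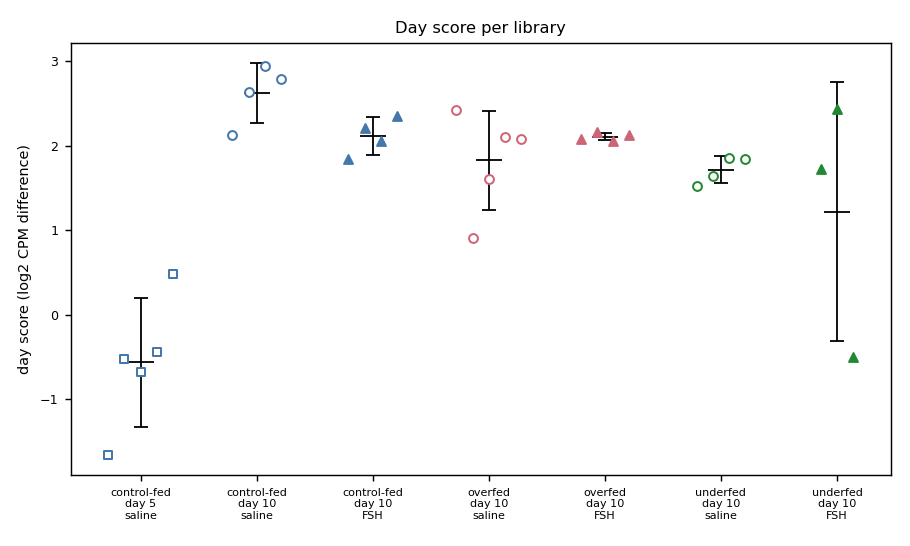
Day score of each library (log2 CPM difference between genes higher and genes lower on day 10) by group, with bars at the mean and SD. UF_10_FSH_147 lies at -0.50, while the other day 10 libraries lie between 0.91 and 2.95.

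The effect of diet alone was read in ewes given saline on day 10. Under underfeeding ENSOARG00000004573 was higher, at 70.6 ± 10.2 CPM against 39.1 ± 3.79 CPM in control-fed ewes (SD, n = 4 each), a log2 fold change of 0.85 (SE 0.14, edgeR adjusted p = 0.0388). The libraries of both diets lay fully apart for this gene, as they did for 10.9% of all tested genes, where chance gives 2.86%. Its level in overfed ewes was 57.0 ± 9.64 CPM (SD, n = 5). It was the only gene past the threshold with edgeR, while 2435 genes had an unadjusted p under 0.05, DESeq2 called 41 genes and limma with sample weights 95. ENSOARG00000013646 had the smallest p of those that did not pass, at 3.58 ± 1.06 against 9.30 ± 1.80 CPM (SD, n = 4 each; log2 fold change -1.36, SE 0.28, edgeR adjusted p = 0.211). The share of squared distance between underfed and control-fed libraries was 25.5% (exact permutation p = 0.0286, the smallest that the splits allow, adjusted p = 0.0857). The call of ENSOARG00000004573 was kept in 6 of 18 alternatives and was lost without any of the 8 libraries except UF_10_C_88.

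Between overfed and control-fed ewes given saline, no gene passed the threshold with edgeR, DESeq2 or limma, and 1030 genes had an unadjusted p under 0.05 with edgeR. ENSOARG00000001039 had the smallest p, at 43.0 ± 3.80 CPM in overfed (SD, n = 5) and 56.4 ± 1.52 CPM in control-fed ewes (SD, n = 4; log2 fold change -0.39, SE 0.09, edgeR adjusted p = 0.698). Between these diets lay 18.4% of the squared distance (exact permutation p = 0.0794, adjusted p = 0.110).

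Between overfed and underfed ewes given saline, edgeR called no gene, with 1902 at an unadjusted p under 0.05. DESeq2 called 126, of which 123 were lower in overfed ewes, and limma with sample weights called 0. ENSOARG00000012486 had the smallest p, at 11.2 ± 2.28 CPM in overfed (SD, n = 5) and 19.5 ± 4.13 CPM in underfed ewes (SD, n = 4; log2 fold change -0.79, SE 0.17, edgeR adjusted p = 0.278). Of the squared distance, 18.1% lay between the diets (exact permutation p = 0.0397, adjusted p = 0.0893).

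FSH was compared with saline within each diet and as the mean of the 3 diets. Over the 3 diets ENSOARG00000002255 was higher under FSH by a log2 fold change of 4.03 (SE 0.76, edgeR adjusted p = 0.0247), and 8 of the 11 FSH libraries lay above the saline mean of their diet. Under saline and FSH its means were 20.8 ± 17.0 and 79.9 ± 113 CPM in control-fed (SD, n = 4 each), 2.89 ± 2.95 (n = 5) and 77.4 ± 85.4 (n = 4) in overfed and 1.27 ± 1.32 (n = 4) and 50.5 ± 60.7 CPM (n = 3) in underfed ewes. ENSOARG00000010485 was higher by 2.78 (SE 0.53, edgeR adjusted p = 0.0247), in 10 of 11 FSH libraries, and its highest value, 70.3 CPM, was in UF_10_FSH_147. On day 5 that gene stood at 17.6 ± 8.81 CPM (SD, n = 5) and in control-fed saline ewes on day 10 at 0.835 ± 0.437 CPM (SD, n = 4). ENSOARG00000014441 was lower by a log2 fold change of -0.58 (SE 0.11, edgeR adjusted p = 0.0247), in 10 of 11 FSH libraries, and was the only gene that fell past the threshold.

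In all, 21 genes passed for the mean of the 3 diets with edgeR, 20 higher and 1 lower under FSH, with a median log2 fold change of 1.38 among those that rose. This balance depended on the tool: DESeq2 called 229 genes, 172 higher and 57 lower, and weighted limma 731, 343 higher and 388 lower. All 21 had fitted changes of the same sign in each diet, which calling them on the mean of these changes favours. For ENSOARG00000014441 the log2 fold change was -0.80 (SE 0.19) in control-fed, -0.82 (SE 0.18) in overfed and -0.11 (SE 0.20) in underfed ewes. At an unadjusted p under 0.05 there were 2395 genes. The calls of ENSOARG00000002255 and ENSOARG00000014441 were lost without any one of NF_10_C_49, NF_10_C_63, NF_10_FSH_143, OF_10_C_20, OF_10_FSH_118, OF_10_FSH_120, UF_10_C_27, UF_10_C_41 and UF_10_FSH_119, and that of ENSOARG00000010485 without any one of NF_10_C_49, NF_10_C_63, OF_10_FSH_118, OF_10_FSH_120, UF_10_C_27 and UF_10_C_41. The call of ENSOARG00000002255 was also lost with limma, with and without sample weights, and that of ENSOARG00000010485 with limma without them. The count of 21 was 0 without UF_10_C_41, 1 to 13 without any other one of those libraries or without NF_10_FSH_110, OF_10_C_77 or UF_10_C_88, and 59 to 244 without UF_10_FSH_147, OF_10_FSH_146, OF_10_FSH_101 or UF_10_C_67.

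**Figure D4:**
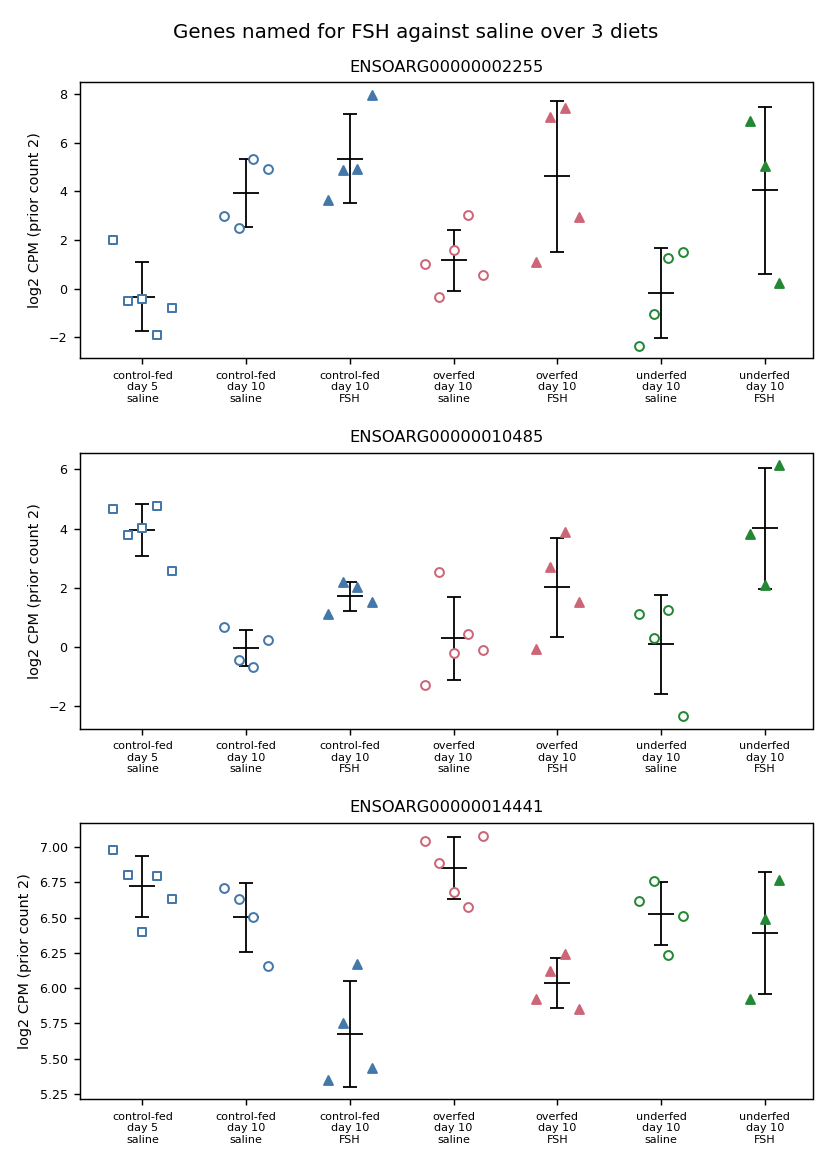
Log2 CPM (prior count 2) of the genes named for FSH against saline over the 3 diets in each library of the 7 groups, with bars at the mean and SD. ENSOARG00000002255 and ENSOARG00000010485 have higher means and ENSOARG00000014441 a lower mean under FSH than under saline in each diet.

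Within control-fed ewes ENSOARG00000013193 had the smallest p for FSH, at 69.8 ± 35.9 against 20.4 ± 6.95 CPM under saline (SD, n = 4 each; log2 fold change 1.77, SE 0.35, edgeR adjusted p = 0.0749), and no gene passed with edgeR. At an unadjusted p under 0.05 there were 3436 genes, the most of the 12 comparisons. DESeq2 called 878 genes, limma with sample weights 3331 and limma without weights 0. Without NF_10_FSH_143 edgeR called 1636. FSH and saline were separated by 25% of the squared distance (exact permutation p = 0.0286, the smallest that the splits allow, adjusted p = 0.0857).

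In overfed ewes ENSOARG00000012583 had the smallest p for FSH, at 1.36 ± 0.164 CPM (SD, n = 4) against 4.77 ± 1.57 CPM under saline (SD, n = 5; log2 fold change -1.80, SE 0.38, edgeR adjusted p = 0.307). No gene passed with edgeR or limma, 1179 had an unadjusted p under 0.05 with edgeR, and DESeq2 called 28. Of the squared distance, 17.7% lay between FSH and saline, where the median over splits was 12.3% (exact permutation p = 0.0714, adjusted p = 0.110).

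In underfed ewes ENSOARG00000015063 had the smallest p for FSH, at 6.95 ± 2.16 CPM (SD, n = 3) against 27.4 ± 5.54 CPM under saline (SD, n = 4; log2 fold change -1.98, SE 0.35, edgeR adjusted p = 0.0814). No gene passed with edgeR or limma, 1647 had an unadjusted p under 0.05 with edgeR, and DESeq2 called 19. The share of squared distance was 20.7%, where the median over splits was 15.7% (exact permutation p = 0.171, adjusted p = 0.193).

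The effect of diet under FSH was compared with control-fed ewes given FSH. In overfed ewes ENSOARG00000001375 had the smallest p, at 30.3 ± 5.44 against 68.7 ± 28 CPM (SD, n = 4 each; log2 fold change -1.18, SE 0.26, edgeR adjusted p = 0.200). No gene passed with edgeR, 2099 had an unadjusted p under 0.05, DESeq2 called 157 and limma with sample weights 344, and edgeR called 531 without NF_10_FSH_143. In underfed ewes ENSOARG00000006903 had the smallest p (edgeR adjusted p = 0.169). It stood at 139.98 CPM in UF_10_FSH_147 and at 2.56 and 0.150 CPM in UF_10_FSH_119 and UF_10_FSH_136, against 0.230 ± 0.351 CPM in control-fed ewes given FSH (SD, n = 4) and 34.3 ± 13.8 CPM on day 5 (SD, n = 5). No gene passed with edgeR or limma for underfed ewes, 2083 had an unadjusted p under 0.05 with edgeR, DESeq2 called 114, and edgeR called 1, 22 and 23 without NF_10_FSH_143, UF_10_FSH_119 and UF_10_FSH_136. The shares of squared distance were 18.9% for overfed and 22.5% for underfed ewes (exact permutation p = 0.200 and 0.0857, adjusted p = 0.200 and 0.110).

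Whether FSH acted differently by diet was tested as the difference of the FSH effects. For underfed against control-fed ewes ENSOARG00000012032 had the smallest p, with a difference in log2 fold change of -2.50 (SE 0.45, edgeR adjusted p = 0.0609). Under FSH it stood at 2.60 ± 0.871 CPM in underfed ewes (SD, n = 3) against 8.12 ± 1.63 CPM under saline (SD, n = 4), and at 7.28 ± 1.53 against 3.98 ± 2.09 CPM in control-fed ewes (SD, n = 4 each). No gene passed for underfed ewes with edgeR, 2706 had an unadjusted p under 0.05, DESeq2 called 217 and limma with sample weights 2. Without NF_10_C_49, NF_10_FSH_143, UF_10_C_27 or UF_10_FSH_119, edgeR called 1, 472, 3 and 4. For overfed against control-fed ewes ENSOARG00000019629 had the smallest p, with a difference of -1.09 (SE 0.24, edgeR adjusted p = 0.505). Its level was 60.2 ± 5.64 CPM under FSH and 35.1 ± 1.62 CPM under saline in control-fed ewes (SD, n = 4 each), and 43.4 ± 7.32 (n = 4) and 53.7 ± 9.72 CPM (n = 5) in overfed ewes. No gene passed for overfed ewes with edgeR, DESeq2 or limma, 1339 had an unadjusted p under 0.05 with edgeR, and edgeR called 3 without NF_10_FSH_143.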

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

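Of the tests in this part, the one on UF_10_C_67 was chosen after the result was seen. In 138 sets of library values of a group (totals, detected genes, scaling, day score and named genes), 9 held a library far from the others of its group, where chance gives about 6.9.

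UF_10_C_41 had 10.4 M counts against 7.0 to 7.48 M in the others of its group. ENSOARG00000004573 was at 6.11 log2 CPM in OF_10_FSH_101 against 5.86 to 5.89 in the others. ENSOARG00000012032 was at 1.91 log2 CPM in OF_10_FSH_101 against 2.13 to 2.17, and ENSOARG00000013193 at 4.78 in OF_10_FSH_120 against 5.19 to 5.21. ENSOARG00000019629 was at 5.2 log2 CPM in OF_10_C_20, against 5.80 to 5.90 in the others. The remaining values rested on 1 or 2 counts where the other libraries of the group had 0 (-2.34 log2 CPM). ENSOARG00000004092 was at -1.82 in NF_10_C_49 and at -1.58 in UF_10_C_88. ENSOARG00000007957 was at -1.40 in NF_10_C_63 and at -1.27 in OF_10_FSH_101.

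For 5 named genes every FSH library of one diet lay above the saline mean of its diet and every FSH library of another diet below. ENSOARG00000013646 had an FSH log2 fold change of -0.78 (SE 0.27) in control-fed and 1.14 (SE 0.30) in underfed ewes, a difference with edgeR adjusted p = 0.159. ENSOARG00000012486 had 0.88 (SE 0.18) in control-fed, 0.22 (SE 0.17) in overfed and -0.63 (SE 0.20) in underfed ewes, with edgeR adjusted p = 0.0609 between underfed and control-fed. ENSOARG00000012032 had 0.87 (SE 0.29) in control-fed and -1.64 (SE 0.34) in underfed ewes, with edgeR adjusted p = 0.0609. ENSOARG00000019629 had 0.78 (SE 0.17) in control-fed and -0.31 (SE 0.17) in overfed ewes, with edgeR adjusted p = 0.505. ENSOARG00000012583 had 0.041 (SE 0.38) in control-fed, -1.80 (SE 0.38) in overfed and 0.64 (SE 0.40) in underfed ewes, and its difference between overfed and underfed ewes was not tested. These genes had been named for their small p in contrasts that share these libraries.

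The 402 genes between day 10 and day 5 were weighed against depth, composition and chance. A median of 73.1% of them were called again with all libraries thinned to the smallest total, which argues against unequal totals as the cause. With median-of-ratios size factors 96.3% were called again. These factors correct composition much as TMM does, so this cannot decide whether the most abundant genes are the cause. Of 100 splits, 2 gave as many genes, the real one and a split with 437 genes that moved NF_5_C_74 to the day 10 side. This share argues against chance but does not exclude it, as it was not adjusted over the comparisons. The squared distance between the days had an adjusted p of 0.0714 (exact permutation). Day of the cycle stays the candidate explanation, as a hypothesis, and which stage NF_5_C_74 held stays open.

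The calls that DESeq2 (878) and limma (3331) made for FSH in control-fed ewes, where edgeR made 0, formed another pattern. With weighted limma, 1 of 35 splits gave as many genes and the highest other gave 2869. That share of 1 in 35 is the smallest that the splits allow, so chance is not excluded. Without sample weights limma called 0 genes, 0% of the weighted count. Without NF_10_FSH_110 and NF_10_FSH_137, which had the highest shares of counts in abundant genes, limma called 4 genes, 0.0831% of the 4816 it called without NF_10_FSH_140 and NF_10_FSH_143. For 94.1% of the genes that edgeR called without NF_10_FSH_143, the underfed saline library UF_10_C_67 deviated from its own group in the direction of the FSH change, against at most 85.3% (NF_5_C_42) in any other saline library outside the comparison. A candidate explanation is a difference between libraries that also occurs without FSH, and a part due to FSH stays open.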

How the results depend on the processing

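The 4 alternatives added after the data were seen were the thinned counts, voom without weights, the bias-adjusted deviances and leaving out the 3 libraries with a TMM factor under 0.8. The cause of the changes below was not tested, except where fewer libraries or genes entered or the threshold was raised. The day comparison (402 genes) gave 256 with the stricter filter, 903 with DESeq2 (401 shared with the 402), 988 with weighted and 415 with unweighted limma (379 and 314 shared), 197 from the compared groups alone, 258 at a log2 fold change of at least 1 and 618 with bias-adjusted deviances, and 68 to 621 with 1 library left out. Underfed against control-fed saline ewes (1 gene) gave 41 with DESeq2, 95 with weighted limma, 3 from the compared groups alone, and 0 with median-of-ratios factors, no filter, the fold minimum, the low-TMM libraries left out or unweighted limma, and 0 to 1 with 1 library left out. Overfed against underfed saline ewes (0) gave 126 with DESeq2. For FSH, control-fed ewes (0) gave 878 with DESeq2, 3331 with weighted limma, 1 from the compared groups alone, 1 with bias-adjusted deviances and 0 to 1636 with 1 library left out. Overfed ewes (0) gave 28 with DESeq2 and 2 with bias-adjusted deviances, and underfed ewes (0) gave 19 with DESeq2, 1 from the compared groups alone and 0 to 1 with 1 library left out. The mean of the 3 diets (21) gave 229 with DESeq2 (21 shared), 731 with weighted limma (20 shared; 343 higher and 388 lower), 13 at the fold minimum, 32 with bias-adjusted deviances, 4 with unweighted limma and 0 to 244 with 1 library left out. Under FSH, overfed against control-fed ewes (0) gave 157 with DESeq2, 344 with weighted limma and 0 to 531 with 1 library left out, and underfed against control-fed ewes (0) gave 114 with DESeq2 and 0 to 23 with 1 left out. The difference of the FSH effect (0) gave 0 to 3 with 1 library left out for overfed ewes. For underfed ewes it gave 217 with DESeq2, 2 with weighted limma and 0 to 472 with 1 left out. Overfed against control-fed saline ewes stayed at 0 in all alternatives, and no named gene changed sign in any. No paired analysis was possible because no library number recurs between groups. The gene list alternatives were not run, as no ID had a name, nor was the share of called genes with the same FSH direction in 2 diets, as no gene passed within a diet. With counts thinned to the smallest total, 5 draws gave 306 to 345 genes for the day comparison and 21 to 31 for the mean of the 3 diets. For FSH in underfed ewes they gave 0 or 1. The exact p of the squared distance between days ranged from 0.00794 to 0.0286 over 12 alternatives. Depth limits genes near the floor: 11 of the 256 genes lower on day 10 had 1 to 3 counts there in all.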

Other observations

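Of the tests in this part, those on the day 5 profile of UF_10_FSH_147, on the swap with genes called anew, on the shared FSH response and on splits at an unadjusted p were chosen after the result was seen.

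Some of the most abundant transcripts varied widely among ewes of one group. Of 238 genes with a mean over 500 CPM, 4 spanned more than 100-fold between libraries, and all 4 were lowest in NF_5_C_3 and highest in OF_10_C_77. ENSOARG00000012585, which ranked 9 by mean level, ran from 86.6 to 15584 CPM. It ranged from 86.6 to 8688 CPM among the day 5 ewes and from 2621 to 6030 CPM among the control-fed saline ewes on day 10, and did not pass the test between these days (log2 fold change 0.27, SE 1.06, edgeR adjusted p = 0.919). In overfed saline ewes it ranged from 388 to 15584 CPM.

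UF_10_FSH_147, from an underfed ewe given FSH and collected on day 10, lay near the day 5 libraries. Of the 402 genes that differed between days, 89.3% were closer to the day 5 mean in this library, against at most 51.5% in any other day 10 library (OF_10_C_28). It had 16047 genes detected and 7.08 M counts, inside the ranges of the other underfed libraries (15560 to 16304 genes, 6.87 to 10.4 M). These values argue against low depth or few detected genes as the cause. Other faults of the library, such as degraded RNA or admixed tissue, were not tested. A swap with a day 5 library would need a partner that looks like day 10. With day genes called without the tested library, the share closer to the day 10 mean was 2.5 to 33.3% in 4 of the 5 day 5 libraries, which argues against them as partners, and 53.1% in NF_5_C_74 (36.8% of the 402 genes, which were called with it). A swap with NF_5_C_74 is therefore open. A ewe at an earlier stage or with early loss of luteal function after stimulation, and a wrong label from outside these groups, stay open as well, as neither progesterone nor ovulation data were analysed here.

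For the hypothesis that FSH shifts the day 10 caruncle further along the course from day 5 to day 10, the prediction fixed beforehand was not met. It asked for a higher day score under FSH than under saline in overfed and underfed ewes. An exact permutation p under 0.05 was needed in at least 1 of these diets. The day score under FSH minus saline was 0.28 in overfed ewes (exact two-sided permutation p = 0.405) and -0.50 in underfed ewes (exact two-sided permutation p = 0.686). Without UF_10_FSH_147 the underfed difference was 0.36 (exact two-sided permutation p = 0.267). Of the 21 genes called for FSH over the 3 diets, 3 were among the 402 day genes, with 0.573 expected by chance. All 3, ENSOARG00000010485 among them, were lower on day 10 and higher under FSH, against the direction of the hypothesis. Both contrasts use the control-fed day 10 saline libraries, which favours such opposite signs. The groups were small, so a shift is not excluded.

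The FSH effects in control-fed and overfed ewes, which share no library, correlated across the 14734 genes with Pearson r = 0.349 and Spearman rho = 0.329 (exact two-sided permutation p = 0.0152 for r, adjusted p = 0.0456 over 3 pairs of diets). Genes are not independent replicates, so the p comes from permuting the libraries within each diet. For control-fed and underfed ewes r was -0.034 (exact two-sided permutation p = 0.847), and for overfed and underfed ewes 0.032 (exact two-sided permutation p = 0.856). Over 20 alternatives the control-fed and overfed r ranged from 0.244 to 0.399, and the permutation p was under 0.05 in 16. The p was 0.0832, 0.0522, 0.0612 and 0.0510 (exact two-sided permutation) without NF_10_FSH_143, OF_10_C_20, OF_10_FSH_118 and OF_10_FSH_120. The other 2 values of r were not stable, from -0.135 to 0.257 over 18 alternatives for control-fed and underfed ewes (lowest permutation p 0.0867) and from -0.126 to 0.198 over 19 for overfed and underfed ewes (lowest permutation p 0.249). The FSH effect had the same sign in both diets for 61.2% of the genes in control-fed and overfed, 46.2% in control-fed and underfed and 48.6% in overfed and underfed ewes. This may point to an FSH response shared by control-fed and overfed ewes, as a hypothesis, and does not show that underfed ewes lack it, and a handling difference that follows the library numbers cannot be told apart from it.

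In overfed ewes given FSH, the libraries paired off. Across genes the Spearman correlations within this group ranged from 0.934 to 0.984, and on the second principal component OF_10_FSH_118 and OF_10_FSH_120 lay at 47.6 and 37.2 while OF_10_FSH_101 and OF_10_FSH_146 lay at -39.0 and -25.0. ENSOARG00000002255 was at 131 and 169 CPM in OF_10_FSH_118 and OF_10_FSH_120 and at 1.94 and 7.43 CPM in OF_10_FSH_101 and OF_10_FSH_146.

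Other splits of the compared libraries were counted for each comparison with edgeR. For underfed against control-fed ewes given saline, 1 of 35 splits gave as many genes as the real one (1, highest other 0). That count rests on 1 gene. For the genes at an unadjusted p under 0.05, 1 of 35 splits also gave as many (2435, highest other 1786). Both shares are the smallest that 35 splits allow and were not adjusted over the comparisons. They make chance less likely but do not exclude it. For FSH over the 3 diets, 2 of 100 splits gave as many genes past the threshold (21, highest other 393). At an unadjusted p under 0.05, 5 of 100 did (2395, highest other 3604). These shares were not adjusted over the comparisons, and the second is not under 0.05, so chance is not excluded. For the comparisons with a real count of 0 the count past the threshold decides nothing about chance, as no split can give fewer. All 100 splits drawn gave as many for overfed against control-fed (highest other 4) and against underfed ewes (1) given saline, for FSH in overfed ewes (6), and for the difference of the FSH effect in overfed (3) and underfed ewes (340). So did all 35 splits for FSH in control-fed (1) and underfed ewes (33), and for overfed (343) and underfed ewes (1029) against control-fed ewes under FSH. At an unadjusted p under 0.05, 1 of 35 splits gave as many genes for FSH in control-fed ewes (3436, highest other 3119). This is again the smallest share that 35 splits allow, without adjustment, and does not exclude chance. For the rest the shares were larger, and chance cannot be excluded there either. In the order above, 8, 8, 18, 13 and 7 of 100 splits gave as many (highest other 1760, 2363, 2690, 2704 and 3305). For FSH in underfed ewes and for the 2 diets under FSH it was 9, 8 and 7 of 35 (highest other 3208, 3023 and 3795). The split with 1029 genes set NF_10_FSH_110, NF_10_FSH_137 and UF_10_FSH_136 against the other 4 libraries, and that with 343 set NF_10_FSH_110, NF_10_FSH_137, OF_10_FSH_101 and OF_10_FSH_146 against the rest, and such counts point to a structure of the libraries other than diet. In the split with 340 genes, 6 of the 8 control-fed day 10 libraries kept their treatment, so it stood close to the real FSH contrast in that diet. In the split with 393 genes, NF_10_C_49, NF_10_C_63 and NF_10_C_69 were set with NF_10_FSH_143 as the FSH side. There the control-fed contrast was nearly the reverse of the real one.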
